A study of Mus musculus with 8 samples.

How the data were processed

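Gene expression was measured by RNA sequencing in cells sorted from mouse bone marrow, 4 wild-type and 4 TOX knockout samples. Per the labels' protocols, cDNA was made from total RNA with a low-input SMARTer kit, turned into Ion Torrent fragment libraries and sequenced on an Ion Proton. The labels do not say which sorted population was used, nor that each sample came from a separate animal. The p-values therefore measure only the spread between these samples, part of which may be technical. Sex-linked genes, given below, show that the samples of each group did not all come from 1 animal. The deposited table gives 1 FPKM value (fragments per kilobase of gene model, scaled to the mapped reads of the library) per gene and library, made by the authors with Cufflinks on the mouse build mm10, per the submitters' processing notes. The Cufflinks version, the aligner and the gene annotation are not given in the sources used here. FPKM is scaled to the mapped reads of a library, so a few abundant transcripts lower the values of all other genes in that library.

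The table held 23846 entries with 23358 distinct symbols. Of these entries, 744 shared a symbol with another entry and were tested separately, and the entry with the highest mean stood for the symbol in gene lists. In 27 entries a spreadsheet had turned the symbol into a date, and these were not renamed. Of 21912 entries whose symbol matched a RefSeq table of assembly GRCm38.p6, 99.4% lay on the same chromosome, and 55.8% had the same start once the printed start was read as counted from 0. Coordinates are therefore given counted from 1, on mm10. The column names of the table give the genotype and a number, 10, 11, 16 or 29, that is not the replicate number of the sample titles. Each column was therefore assigned to its group only, and libraries are called here by that number. The column names also carry barcodes in 2 runs, 17 to 20 for libraries 10 and 16 and 40 to 43 for libraries 29 and 11, with 2 libraries of each group in each run.

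Values were used as deposited, as log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 8 libraries were tested, 10693 in all. Groups were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a mean-variance trend and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called changed. Every log2 fold change is TOX knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes. An exact two-sided permutation test of 4 against 4 libraries cannot give a p below 0.0286. Lists of genes for lymphoid, myeloid, erythroid and stem cell types, signalling, cell cycle, stress and sample checks were fixed before the data were examined. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 23 lists, and again with an estimated correlation and with fry. With preset correlation 13 lists passed, with an estimated correlation 0 passed (lowest adjusted p = 0.176), and fry called 3. Lists with fewer than 3 measured members had no set test.

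The genes named in the text followed a rule written before the data were examined. It took Tox, up to 12 genes in each direction with the largest fold change among called genes whose groups did not overlap, and up to 4 called members of each list or, where none was called, the 2 with the smallest p. It also took 12 genes of ILC and lymphoid development whatever their p, and predicted or unnamed transcripts, 18 of those called, were counted but not named. Genes named outside this rule are marked where they appear, and 1 gene that the rule took is not reported here.

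The files hold no read counts, so the absolute depth is unknown. The steps between low FPKM values gave the relative depth of libraries within each barcode run, with a closure error of at most 0.04 on the log2 scale. Relative to wild-type library 10, the depth was 0.717 in knockout library 10, 0.835 in wild-type library 16 and 1.41 in knockout library 16. Relative to wild-type library 29, it was 0.707 in knockout library 29, 0.801 in wild-type library 11 and 0.895 in knockout library 11. Depth was not compared across runs. No 2 libraries held identical values.

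The test was run on simulated data with the means and spread of these libraries over the same 10693 genes, 200 of them, with a mean log2 value above 2, changed. It recovered 4% of genes changed by 1 on the log2 scale, 54% of those changed by 2, 76% of those changed by 3 and 92% of those changed by 4, with 6 false calls. Alternatives covered the pseudocount, the filter on low values, scaling between libraries, library weights, the variance model, the thresholds, the set test and each library left out in turn. A fit with the shared column number as a block, the barcode run as a covariate, each run alone, and knockout libraries 16 and 29 left out together were added after the data were seen.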

Results

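RNA-seq profiles were compared between cells sorted from the bone marrow of wild-type mice and of mice lacking TOX, a nuclear HMG-box protein expressed in developing lymphocytes, with 4 libraries per group. As the series title states, the comparison bears on how TOX acts in the formation of innate lymphoid cell (ILC) progenitors. ILCs are lymphocytes without rearranged antigen receptors and comprise NK cells, ILC1, ILC2, ILC3 and lymphoid tissue inducer (LTi) cells. Values were FPKM as deposited, with sums of 296777 to 365906 per wild-type library and 208351 to 632604 per knockout library. An FPKM of at least 1 was reached by 10425 to 10481 genes in the wild-type libraries, and by 10115, 10600, 7328 and 9263 genes in knockout libraries 10, 11, 16 and 29.

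Tox itself (chromosome 4, 6687386 to 6990723, mm10) had a mean FPKM of 110 ± 13.8 (SD, n = 4) in wild type and 0.904 ± 1.02 (SD, n = 4) in TOX knockout. The 4 wild-type values were 107, 123, 92.4 and 119 in libraries 10, 16, 29 and 11. The knockout values were 2.34, 0.928, 0.242 and 0.107 in the same order of library numbers. The log2 fold change was -6.00 (SE 0.41, limma adjusted p = 8.48e-06), a difference of 64.1-fold, and every library matched its label.

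With the values as deposited, most genes called changed in TOX knockout were lower. Of 10693 genes tested, 184 fell and 21 rose at an adjusted p under 0.05, against 119 and 93 with median-ratio scaling and 145 and 116 with quantile normalization, and 146 of the 184 fell by at least 4-fold. Arg1, which encodes arginase 1 and is expressed in ILC2 and their precursors, fell the most, from 95.8 ± 15.6 to 0.114 ± 0.215 FPKM (SD, n = 4 each), a log2 fold change of -6.45 (SE 0.35, adjusted p = 1.70e-06). Rxrg, encoding the retinoid X receptor gamma, had a mean of 56.2 ± 8.27 in wild type and was listed at 0 in 3 knockout libraries and at 0.0028 in library 11. Pdcd1, which encodes the inhibitory receptor PD-1, fell from 89.6 ± 34.2 to 1.23 ± 2.43, and Icos, a costimulatory receptor, from 131 ± 42.6 to 3.03 ± 2.81. Bcas1, Fgf15, Pgam2, Stab2 and Lrrc52 also fell, with log2 fold changes between -4.97 and -4.06.

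Among the 21 genes that rose, Slpi, a secreted inhibitor of neutrophil proteases, rose from 7.07 ± 3.91 to 76.5 ± 42.98 FPKM (log2 fold change 3.29, SE 0.56, adjusted p = 0.00887). Lmo2, a transcriptional cofactor of blood progenitors, rose from 11.5 ± 6.79 to 93.0 ± 51.4 (2.93, SE 0.49, adjusted p = 0.00762). Stfa2l1 was listed at 0 in all 4 wild-type libraries and at 39.5, 5.20, 14.2 and 38.7 in knockout libraries 10, 11, 16 and 29 (adjusted p = 0.00147). Clec7a, the beta-glucan receptor Dectin-1, Cd300lf, Wfdc17, Slfn4, Plbd1, Orm1, Klf4, Ndrg1 and Tspan8 rose with log2 fold changes between 2.01 and 3.85. Stfa2l1 and Slfn4 have closely similar neighbours, between which reads may have been split in the authors' quantification.

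All 205 genes had non-overlapping groups, as did 1295 of the tested genes (12.1%, against 2.86% by chance). The median log2 fold change of all tested genes was -0.52, and with median-ratio scaling, which brought it to -0.04, 119 genes fell and 93 rose (43.9% of calls, against 10.2% as deposited). Of the genes above, 115 of the 184 that fell and 19 of the 21 that rose were called in the same direction with that scaling, and Tspan8 was not (adjusted p = 0.0540). The count was 89, 82, 123 and 87 without wild-type libraries 10, 11, 16 and 29. It was 165, 654, 351 and 106 without knockout libraries 10, 11, 16 and 29. Within the barcode runs, 2 against 2 libraries, 5 genes changed in the first and 95 in the second. Across genes the fold changes of the runs correlated at r = 0.54, where genes are not independent replicates.

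**Figure D1:**
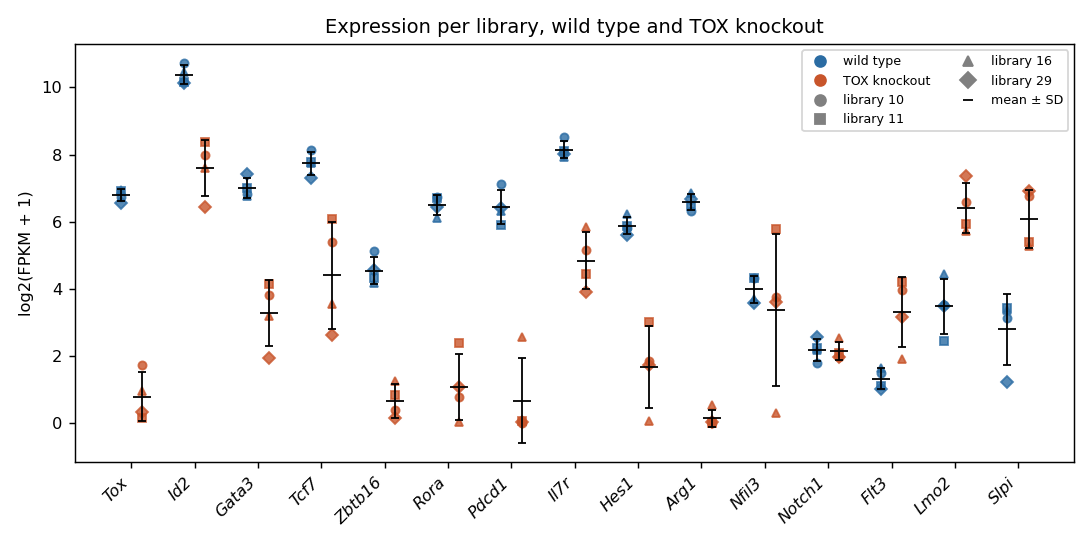
Expression of 15 genes named in the text as log2(FPKM + 1), with a point per library (shape, library number), blue for wild type and orange for TOX knockout, and black lines for the mean ± SD of 4 libraries. Tox, Id2, Gata3, Tcf7, Zbtb16, Rora, Pdcd1, Il7r, Hes1 and Arg1 lie lower in all 4 knockout libraries than in any wild-type library. Lmo2, Slpi and Flt3 lie higher, of which Flt3 was not called changed with values as deposited. Nfil3 and Notch1 overlap between groups.

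Genes of the ILC progenitor regulator list were lower in TOX knockout cells. Beside transcription factors, the list holds surface receptors and integrins, Pdcd1 among them. Of 16 measured, 9 fell and none rose, and 12 fell when adjusted over the list alone. Zbtb16, which encodes PLZF and marks ILC precursors, fell from 23.1 ± 7.43 to 0.645 ± 0.582 FPKM (log2 fold change -3.89, SE 0.41, adjusted p = 3.52e-04), and the related family member Tox2 fell from 11.8 ± 4.06 to 0.0872 ± 0.0923. Gata3 and Tcf7, transcription factors of early T cell and ILC development, fell from 129 ± 28.3 to 10.2 ± 6.05 and from 217 ± 50.5 to 30.6 ± 28.3. Id2, an inhibitor of E proteins required for ILCs, fell from 1349 ± 267 to 215 ± 103 (-2.78, SE 0.42, adjusted p = 0.00426), and Rora, a nuclear receptor needed by ILC2, from 90.6 ± 17.9 to 1.51 ± 1.85. Nfil3, a transcription factor that acts early in the ILC lineage, was at 15.3 ± 4.45 and 19.4 ± 23.6 and did not pass (adjusted p = 0.645), with knockout values from 0.239 in library 16 to 53.9 in library 11.

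The median log2 fold change of the ILC progenitor list was -2.55 and differed from that of all genes by -2.03, with a camera adjusted p of 4.17e-12 (adjusted p = 0.176 with an estimated correlation). Tested with fry against no change, the list had an adjusted p of 0.00176. Without knockout libraries 16 and 29, 11 of its members fell, with a median of -2.21, and with median-ratio scaling 7 fell, with a median of -1.96. In the same libraries granulocyte genes made up 3.86 to 7.89% of summed FPKM in knockout and 0.0815 to 2.71% in wild type. The TOX family list had 2 measured members, Tox2, which fell, and Tox4, which did not pass (log2 fold change -0.20, adjusted p = 0.779).

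Genes of ILC2 and of ILC3 and LTi cells were lower as well. Of 9 measured ILC2 genes 4 fell, and 6 when adjusted over the list alone. Il1rl1, the IL-33 receptor, fell from 34.5 ± 18.6 to 2.90 ± 3.71 FPKM and Il17rb, the IL-25 receptor subunit, from 79.6 ± 24.9 to 9.25 ± 8.71, beside Arg1 and Hes1. Of 10 measured ILC3 and LTi genes 4 fell, and 7 fell and 1 rose when adjusted over the list alone. Cxcr5, Tnfsf11 and Ltb fell with log2 fold changes of -2.92, -2.62 and -2.18. The camera adjusted p was 4.45e-07 for the ILC2 list and 0.00534 for the ILC3 and LTi list (adjusted p = 0.176 with an estimated correlation for each), and fry, which tests against no change, gave 0.00137 and 0.00245. With median-ratio scaling Il17rb and Ltb did not pass (adjusted p = 0.114 and 0.0711).

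Among effector genes of NK cells and ILC1, single genes fell while the list did not pass. Eomes, a T-box factor of NK cells, fell from 21.8 ± 6.90 to 1.35 ± 1.91, and Klrb1b, an NK cell receptor in a cluster of similar genes, from 8.20 ± 4.33 to 0.962 ± 1.01, the latter not with median-ratio scaling (adjusted p = 0.107). These were the 2 of 16 measured that fell, against 4 adjusted over the list alone (list, camera adjusted p = 0.639).

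Among lymphoid progenitor genes, Il7r, the receptor for interleukin 7, fell from 285 ± 54.2 to 31.5 ± 18.9 FPKM (log2 fold change -3.30, SE 0.42, adjusted p = 0.00114). Ccr9, a homing receptor, fell from 25.8 ± 6.48 to 3.06 ± 1.09 and Ikzf2, an Ikaros family factor, from 39.5 ± 6.92 to 10.1 ± 4.37, while Lmo2 rose. Flt3, a receptor of multipotent and lymphoid progenitors, was at 1.53 ± 0.548 and 10.7 ± 6.65 and did not pass as deposited (adjusted p = 0.0726) but did with median-ratio scaling (adjusted p = 0.00661). Of 17 measured 1 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.295). The balance turned to 3 that rose and 2 that fell with median-ratio scaling, where the median was 0.36 against -0.16 as deposited, and to 5 and 3 without knockout libraries 16 and 29. Rag1, a recombinase of developing B and T cells, stayed under the filter with values of 0.0206 to 0.323 in wild type and 0.0131 to 1.64 in knockout.

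The T lineage list had 3 of 15 measured members that fell, and 7 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.410). Without knockout library 10 the list passed in camera and in fry (adjusted p = 0.0466 and 0.0416). Txk, a Tec family kinase, fell from 28.3 ± 5.83 to 2.08 ± 0.522, Skap1, a T cell adaptor, from 32.8 ± 10.3 to 4.70 ± 3.17, and Cd28 from 6.57 ± 3.09 to 0.936 ± 0.810. In the list of cytokine receptors and JAK-STAT genes 4 of 28 fell, and 8 when adjusted over the list alone. They were Il7r, Il2rg, the common gamma chain, at 274 ± 65.2 and 61.4 ± 53.8, Socs1, at 43.2 ± 13.8 and 5.91 ± 4.83, and Il12rb1, at 9.39 ± 3.498 and 1.42 ± 0.797 (list, camera adjusted p = 0.159). This list passed as lower in camera under 5 of 24 other settings (adjusted p from 0.0012 to 0.0490), and in fry with a mean FPKM of at least 5 (0.0168) and without knockout library 11 (0.0326). Of 16 chemokine receptors, integrins and homing genes Ccr9 and Cxcr5 fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.295). With a mean FPKM of at least 5 the homing list passed in camera (adjusted p = 0.0109), and fry called it under 4 of 24 settings, among them without knockout library 10 (0.0416) and without knockout libraries 16 and 29 (0.00625). Skap1, Cd28, Ikzf2, Socs1 and Il12rb1 did not pass with median-ratio scaling, with adjusted p between 0.0634 and 0.0992.

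In the Notch pathway Hes1, a transcriptional repressor induced by Notch, fell from 58.6 ± 10.7 to 3.01 ± 2.97 FPKM (log2 fold change -4.22, SE 0.54, adjusted p = 0.00114). It was the only 1 of 15 measured members that fell, against 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0601, fry adjusted p = 0.1002). It passed as lower in camera with no filter (adjusted p = 0.0381) and with a mean FPKM of at least 5 (0.0478), and it also passed in fry with median-ratio scaling (0.00427), with quantile normalization (0.00424) and without knockout library 11 (0.0403). The receptor Notch1 was at 3.64 ± 1.04 and 3.46 ± 0.884, with a log2 fold change of -0.05 as deposited and 0.46 with median-ratio scaling (adjusted p = 0.944 and 0.588).

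**Figure D2:**
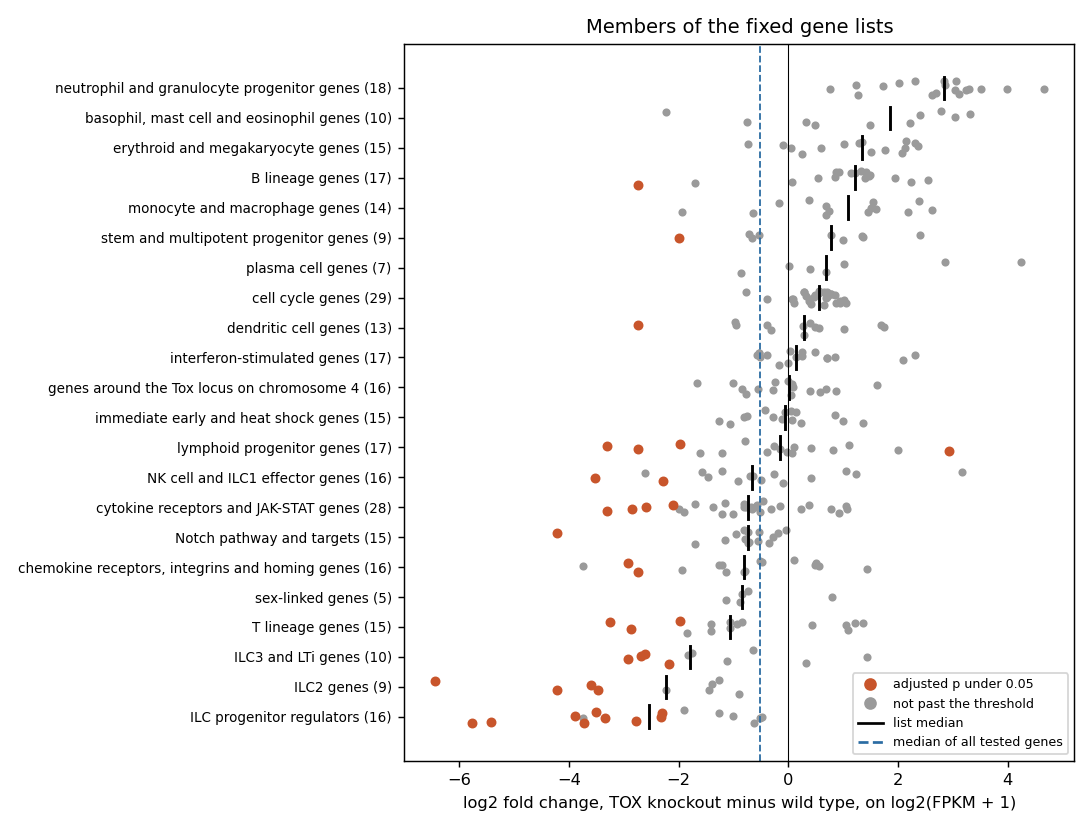
Log2 fold change (TOX knockout minus wild type, on log2(FPKM + 1)) of each measured member of 22 fixed gene lists, with the number measured in parentheses, orange for genes past an adjusted p of 0.05 and grey for the others. Black bars are list medians, from -2.55 for ILC progenitor regulators to 2.84 for neutrophil and granulocyte progenitor genes, and the dashed line is the median of all tested genes, -0.52.

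Lists of other bone marrow lineages ranked above other genes in camera. No member of them rose past the test over all genes as first run, with a mean FPKM of at least 1 as the filter and values as deposited. This covers listed genes only. Slpi, Stfa2l1, Wfdc17, Slfn4, Cd300lf, Plbd1, Orm1 and Clec7a rose in that test and are on none of these lists. Members of the lists rose under other settings. Neutrophil and granulocyte progenitor genes had a median log2 fold change of 2.84, and 0 of 18 measured passed over all genes while 14 rose when adjusted over the list alone (camera adjusted p = 3.46e-22, adjusted p = 0.176 with an estimated correlation). Camp, an antimicrobial peptide of neutrophil granules, was at 296 ± 280.1 and 1703 ± 1039.6 FPKM (adjusted p = 0.0776), and Mmp8, neutrophil collagenase, at 9.28 ± 3.59 and 47.5 ± 32.4 (adjusted p = 0.0669). Monocyte and macrophage genes had a median of 1.10, with 3 of 14 that rose and 1 that fell adjusted over the list alone and 0 over all genes (camera adjusted p = 4.01e-07, adjusted p = 0.176 with an estimated correlation). Csf1r was at 0.354 ± 0.484 and 2.97 ± 0.714 (adjusted p = 0.0658), and Ccr2 at 141 ± 8.57 and 43.1 ± 28.7 (adjusted p = 0.0522). In the basophil, mast cell and eosinophil list 4 of 10 rose and 1 fell adjusted over the list alone and 0 over all genes (median 1.86, camera adjusted p = 1.48e-06, adjusted p = 0.176 with an estimated correlation). Fcer1a was listed at 0 in 3 wild-type libraries and at 0.0899 in library 16, and at 0, 16.03, 11.5 and 10.7 in knockout libraries 10, 11, 16 and 29, and Ms4a2 was at 0.864 ± 1.36 and 9.76 ± 12.02. Of neutrophil genes 2, 2 and 6 rose over all genes without wild-type library 16, knockout library 11 or knockout library 16. With median-ratio scaling 2 rose, with libraries scaled to the same sum 5, in the second barcode run alone 9 and with library weights 11. Of monocyte genes 3 and 2 rose without knockout library 11 or 16 and 5 with library weights. With all libraries unscaled and a filter of an FPKM of at least 1 in 4 libraries, 1 monocyte gene rose. Of basophil genes 2 and 1 rose without knockout library 10 or 16, with 1 under median-ratio scaling and 2 with library weights. The mean log2(FPKM + 1) of the neutrophil list was 4.88 in knockout library 16 and 6.01 in wild-type library 16, against 6.51 to 8.11 in the other knockout and 1.81 to 4.34 in the other wild-type libraries. These means were not scaled between libraries. The ribosomal protein list was also lower in knockout library 16 than in wild-type library 16 (6.55 and 7.46).

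Erythroid and megakaryocyte genes had a median of 1.34 and 0 of 15 past the threshold by either adjustment, including adjusted over the list alone (camera adjusted p = 6.07e-10, adjusted p = 0.176 with an estimated correlation). Without knockout library 11, 3 of them rose over all genes, and 2 with library weights. Slc4a1, the red cell anion exchanger, was at 7.06 ± 7.16 and 49.0 ± 52.0, and Car2 at 94.4 ± 38.3 and 327 ± 259. Globin transcripts held 3.67, 3.42, 14.8 and 5.52% of summed FPKM in wild-type libraries 10, 11, 16 and 29, and 25.6, 6.17, 20.9 and 58.6% in the knockout libraries of the same numbers. The granulocyte list held 0.0815 to 2.71% in wild type and 3.86 to 7.89% in knockout. The granulocyte shares did not overlap between the groups, and the globin shares did.

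**Figure D3:**
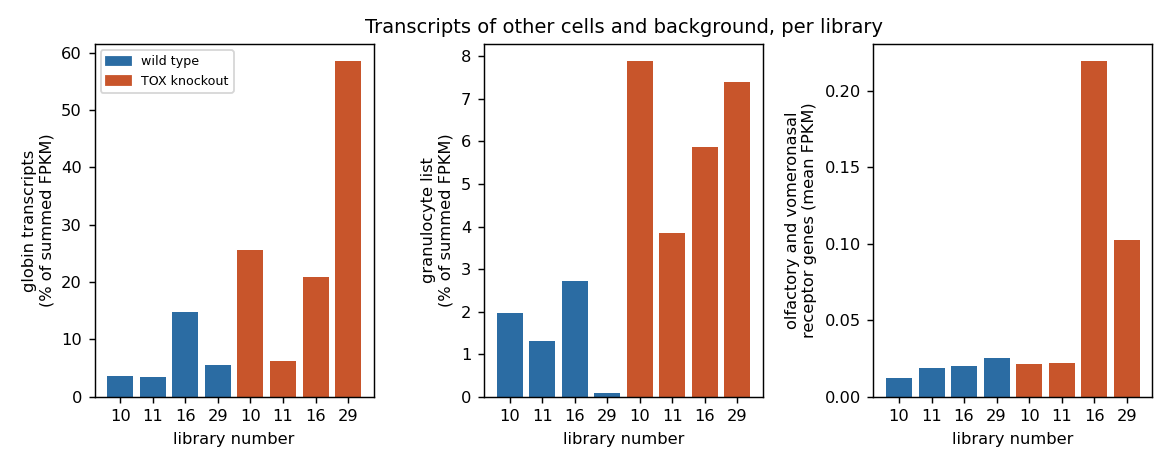
Share of summed FPKM (%) from globin transcripts and from the granulocyte list, and mean FPKM of olfactory and vomeronasal receptor genes, with a bar per library, blue for wild type and orange for TOX knockout. Granulocyte shares of the 4 knockout libraries (3.86 to 7.89%) lie above those of wild type, and the receptor genes reach 0.220 in knockout library 16 and 0.102 in library 29.

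B lineage genes had a median of 1.21, and of 17 measured 1 fell, with 2 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 3.79e-07, adjusted p = 0.257 with an estimated correlation). The member that fell was Lef1, at 28.5 ± 5.99 and 3.81 ± 2.35, a Wnt pathway factor that T and ILC precursors also express. Ebf1, which specifies B cells, stayed under the filter, with 0.0384 to 1.12 in wild type and 0.00377 to 4.81 in knockout. Plasma cell genes had a median of 0.69 and 0 of 7 past the threshold, with 2 that rose adjusted over the list alone (camera adjusted p = 2.03e-04, adjusted p = 0.176 with an estimated correlation). Mzb1 was at 9.83 ± 11.9 and 67.6 ± 68.2, and Igj, the J chain, at 40.3 ± 46.6 and 230.0 ± 182. Of 13 dendritic cell genes 1 fell, Ccr9, against 2 that rose and 1 that fell adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.0332, adjusted p = 0.589 with an estimated correlation). Of 9 stem and multipotent progenitor genes 1 fell, Hlf, from 9.35 ± 4.24 to 1.45 ± 0.703, against 1 that rose and 1 that fell adjusted over the list alone, with a median of 0.78 (camera adjusted p = 0.0143, adjusted p = 0.402 with an estimated correlation). The dendritic list did not pass without knockout library 10 (adjusted p = 0.0640), nor the stem cell list without knockout library 11 (0.0658) or with median-ratio scaling (0.0982), where Hlf did not pass either (0.0874). With median-ratio scaling 1 B lineage, 2 dendritic cell and 1 stem cell gene rose over all genes, and so did as many of each without knockout library 16. Without knockout library 11, 2 B lineage genes rose, and without wild-type library 16, 1 plasma cell gene. With library weights 3 B lineage, 3 dendritic cell, 2 stem cell and 1 plasma cell gene rose.

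Cell cycle genes lay higher as a list, with a median of 0.56 and 0 of 29 past the threshold by either adjustment, including adjusted over the list alone (camera adjusted p = 4.17e-12, adjusted p = 0.188 with an estimated correlation). Mki67 was at 19.0 ± 7.57 and 38.6 ± 10.3 and Mcm3 at 25.9 ± 3.83 and 45.1 ± 8.52. Mcm3 passed with median-ratio scaling (limma adjusted p = 0.0348), and 2 cell cycle genes rose with library weights. Fry called the cell cycle list with quantile normalization (adjusted p = 0.0412). Interferon-stimulated genes had a median of 0.13, which lies 0.65 above that of all genes, and 0 of 17 passed, against 2 that rose adjusted over the list alone (camera adjusted p = 2.15e-04, adjusted p = 0.272 with an estimated correlation). Ifi27l2a was at 42.96 ± 55.5 and 138 ± 54.3, and Rsad2 at 8.26 ± 6.51 and 41.8 ± 30.8. With library weights 2 interferon-stimulated genes rose over all genes, and 1 without wild-type library 16. Fry called this list with quantile normalization (adjusted p = 0.0182), and camera did not call it with no filter (adjusted p = 0.0777). Of 15 immediate early and heat shock genes, 0 passed by either adjustment (median -0.06, camera adjusted p = 0.0601), with Hspa8 at 235 ± 83.2 and 133 ± 92.5 and Jun at 13.7 ± 8.78 and 10.9 ± 17.7. The immediate early list passed as higher in camera under 8 of 24 settings, among them without wild-type library 11 (adjusted p = 5.20e-04), knockout library 10 (0.00562) or knockout library 29 (0.0237). Of 73 cytosolic ribosomal protein genes 0 passed by either adjustment (median -0.33, camera adjusted p = 0.330), with Rps27 at 156 ± 59.4 and 44.4 ± 51.2 and Rpl3 at 232 ± 24.7 and 114 ± 82.7. The ribosomal list passed in camera as higher with median-ratio scaling (median 0.28, adjusted p = 6.92e-04) and without wild-type library 29 (median -0.17, adjusted p = 0.0312), and as lower with no filter (median -0.31, adjusted p = 0.0189). No mitochondrially encoded gene was measured here.

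Around the Tox locus on chromosome 4, 0 of 16 measured genes passed by either adjustment (median 0.02, camera adjusted p = 0.0504). As a list they passed as higher in camera under 12 of 24 settings (adjusted p from 0.00854 to 0.0496), among them without wild-type library 10, 11 or 16 and without knockout library 29. With an estimated correlation the list did not pass in camera (adjusted p = 0.598). Car8 was at 0.290 ± 0.201 and 3.37 ± 2.20 (adjusted p = 0.0945) and Ints8 at 8.48 ± 1.56 and 2.65 ± 2.73 (adjusted p = 0.126). Of 5 sex-linked genes 0 passed by either adjustment, and the list's median of -0.84 and mean of -0.56 were negative while camera placed it above other genes (adjusted p = 0.672). Xist, expressed from the inactive X chromosome, was at 34.6 and 4.93 in wild-type and knockout library 16, where Kdm5d and Uty of the Y chromosome were at 0 to 0.0147. Xist was at 3.76 and 11.3 in knockout libraries 29 and 11, where the Y-linked Ddx3y was at 8.29 and 16.02. It was at 0.00774 to 0.0565 in the other 4 libraries, where Ddx3y was at 21.4 to 43.6. By these genes wild-type and knockout library 16 were female and those 4 libraries male, so each group held samples of different animals. Knockout libraries 29 and 11 held Xist beside Y-linked transcripts. Whether cells of both sexes were mixed in them was not tested. Tox4, Xist and Ddx3y lie outside the rule for named genes and were chosen after their values were seen.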

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

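The tests of globin and granulocyte transcripts, of the libraries with background, of the cell mix, of depth and of the effect of TOX itself on receptor genes were chosen only after the results they bear on had been seen. Of 145 groups of 4 libraries tested for a library far from the others, 14 had one. Chance gives about 5% for normally spread values. That rate does not hold where the other libraries are tied at 0, since any value above 0 is then flagged. This was so for Rxrg and Lrrc52 in knockout and Fcer1a in wild type, so the count cannot be set against 5%.

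Among genes that fell, knockout library 16 was apart for Arg1 (0.436 FPKM, others 0 to 0.0135) and Pdcd1 (4.88, others 0 to 0.0467). Rxrg was at 0.0028 in knockout library 11 and Lrrc52 at 0.0531 in knockout library 29, with 0 in the other 3 knockout libraries for each. Skap1 was at 0.104 in knockout library 29 against 5.52 to 7.37 in the others. In wild type, library 29 was apart for Eomes (32.1, others 17.5 to 19.1), Txk (37.0, others 24.6 to 26.3) and Slpi (1.34, others 7.84 to 9.78), and library 10 for Klrb1b (14.7, others 5.75 to 6.19). Fcer1a was at 0.0899 in wild-type library 16, with the other 3 at 0, and at 0 in knockout library 10, with the others at 10.7 to 16.03. Ifi27l2a was at 219 in knockout library 29, with the others at 105 to 115. Kdm5d was at 0 in wild-type library 16, with the others at 6.18 to 7.60, and Uty at 0 in knockout library 16, with the others at 2.68 to 3.27. Both genes lie on the Y chromosome, and these libraries were female by their sex-linked genes.

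Olfactory and vomeronasal receptor genes, 1438 in the table and normally silent outside sensory neurons, had a mean FPKM of 0.220 in knockout library 16 and 0.102 in knockout library 29, against 0.0120 to 0.0251 in wild type. In library 16 this was 10.3 times the highest other library of its barcode run, which argues against depth, since FPKM is scaled to depth. Loss of TOX as such is argued against by 2 knockout libraries, 10 and 11, that did not exceed every wild-type library. The argument is weak within the barcode runs. Knockout library 10 (0.0213) exceeded both wild-type libraries of its run (0.0120 and 0.0200). Only knockout library 11 (0.0222) lay below a wild-type library of its run, library 29 (0.0251). On 14 of 14 chromosomes with at least 10 of these genes, the mean in knockout library 16 was above all wild-type libraries. Knockout library 29 was above them too, except on chromosome 17 (0.0528, against 0.0808 in the highest wild-type library). Genomic DNA or another even background may therefore be the source and stays open. Knockout library 16 also had the fewest genes at an FPKM of 1 or more, 7328.

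The lower ILC progenitor list could come from abundant globin and granulocyte transcripts, from background in 1 or 2 knockout libraries, from other cells in the knockout sort, or from loss of TOX in the sorted cells. With median-ratio scaling, which moved the median of all genes from -0.52 to -0.04, the list's median was -1.96 and fry's adjusted p 0.00427, which argues against the first as the whole cause. Without knockout libraries 16 and 29 the median was -2.21 (fry adjusted p = 0.00398), which argues against the second. Of 7 lists of other lineages, 0 had a mean higher in all 4 knockout libraries than in all 4 wild-type libraries, although camera placed all 7 above other genes. Knockout library 16 lay below wild-type library 16 for the neutrophil list (4.88 and 6.01). These means were unscaled, and the median-ratio scaling factor was 0.422 in knockout library 16 against 1.19 in wild-type library 16. The granulocyte share was 5.86% in the former and 2.71% in the latter. The count of 0 therefore cannot speak against a different mix of cells. A different mix of cells and a change within the sorted cells cannot be told apart, because the table holds bulk values of a sort that the labels do not define.

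Of the 35 splits of the libraries into 4 and 4, 1 gave as many as 205 genes, the real one, and the highest of the others gave 6. Every other split mixed the genotypes, which widened its spread and lowered its count. With so few splits, chance division of the libraries is argued against but not excluded.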

How the results depend on the processing

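The block, the barcode settings and the joint removal of knockout libraries 16 and 29 were chosen only after the data were seen. Tox and the ILC progenitor list kept their direction under every setting run. Counts are given as changed, then rose and fell, against 205, 21 and 184. They were 106, 10 and 96 with a pseudocount of 0.1, 74, 7 and 67 with no filter (67 genes shared), 116, 10 and 106 with a mean FPKM of at least 5, and 336, 35 and 301 when every library was scaled to the same sum. They were 728, 271 and 457 with library weights and 400, 65 and 335 at an adjusted p under 0.1. Median-ratio scaling gave 93 that rose and 119 that fell, and quantile normalization 116 that rose. Leaving out 1 library gave 82 to 654 changed, 6 to 126 rose and 75 to 578 fell. The count was 89, 82, 123 and 87 without wild-type libraries 10, 11, 16 and 29. It was 165, 654, 351 and 106 without knockout libraries 10, 11, 16 and 29. Without knockout libraries 16 and 29 together 286 changed, of which 107 rose. The first barcode run alone gave 5, 0 and 5, and the second 95, 35 and 60, with fewer libraries. Lists past the threshold numbered 0 with an estimated correlation and 3 with fry, against 13. Over 24 settings the camera call of 11 of 23 lists and the fry call of 12 changed at least once. Calls gained in camera came under 12 settings for the genes around Tox, 8 for immediate early, 5 for cytokine receptor, 2 for T lineage and 1 for homing genes, and calls lost under 5 for dendritic, 4 for stem cell and 1 each for interferon-stimulated and ILC3 genes. The ILC progenitor, ILC2 and ILC3 lists lost their fry call in each run alone (adjusted p = 0.0951 and 0.342). Ribosomal protein genes, not called as deposited, passed as lower with no filter, where their median minus that of all genes was -0.30 (adjusted p = 0.0189), and as higher with median-ratio scaling (adjusted p = 6.92e-04), in the first run alone (0.00921) and without wild-type library 29 (0.0312). The Notch list passed in camera with no filter (0.0381) and with a mean FPKM of at least 5 (0.0478), and in fry with median-ratio scaling (0.00427), quantile normalization (0.00424) and without knockout library 11 (0.0403). With all libraries as deposited, fry placed dendritic cell genes lower although their median was 0.28 (adjusted p = 0.950). Apart from the removal of libraries and genes, the cause was not tested. Of 47 called genes named here besides Tox, 21 to 47 stayed called under the settings with all libraries, 29 to 47 with 1 library left out, 37 without knockout libraries 16 and 29, and 3 and 27 in the first and second run alone. No called gene changed sign, and at most 1 uncalled gene did per setting. The planned block on the replicate numbers of the sample titles was not run, because the columns carry none. A replicate block on the shared column number gave 344 changed and 77 that rose, among them 8 neutrophil, 4 basophil, 2 erythroid, 2 plasma cell, 2 B lineage and 1 stem cell gene, of lists with 0 that rose without it. The deviations of same-numbered libraries correlated at r = 0.0387, 0.258, 0.00621 and -0.0206 for 10, 11, 16 and 29, over 0.1 for 11 alone. Libraries 10 and 11 correlated best with their own number and 16 and 29 did not. These correlations did not decide the main test. It was set without pairs beforehand, because the labels do not say that a replicate number marks a shared mouse, litter or day. Other values were shared by number. Only wild-type and knockout library 16 lacked the Y-linked Ddx3y (0 and 0.0193 FPKM). Immediate early and heat shock genes had their highest mean log2(FPKM + 1) in wild-type and knockout library 11 (5.403 and 6.119). Xist differed between wild type and knockout of number 29 (0.0565 and 3.76) and number 11 (0.0148 and 11.3). Whether the number marks pairs therefore stays open. Depth in reads is unknown, and changes of 1 on the log2 scale were recovered in 4% of simulated genes, so a missed call does not show that a gene was unaltered.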

Other observations

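The count of neighbouring pairs that do not overlap was chosen only after the first count of neighbours had been seen, and the genes named in this part were chosen after their values were seen.

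In limma's test Bcl2, an inhibitor of apoptosis, fell from 174 ± 42 to 21.7 ± 20 FPKM (log2 fold change -3.53, SE 0.65, adjusted p = 0.0156, n = 4 each). Ikzf3, which encodes Aiolos, fell from 25.3 ± 9.3 to 1.74 ± 1.6 and Maf, a transcription factor of T cells and ILCs, from 60.6 ± 16 to 7.26 ± 2.6. Nmur1, the neuromedin U receptor found on ILC2, was at 14.9 ± 6.8 in wild type and 0.0017 ± 0.0034 in knockout (-3.88, SE 0.42, adjusted p = 3.73e-04). Cysltr1, a leukotriene receptor, and the chemokine receptor Ccr8 fell with log2 fold changes of -3.42 and -3.34, and Csf2, which encodes GM-CSF, fell from 12.2 ± 3.8 to 0.928 ± 1.5. Dll1, a Notch ligand, fell from 7.14 ± 2.5 to 0.150 ± 0.29. The clock genes Arntl and Nr1d1 fell with log2 fold changes of -1.89 and -2.01, but did not pass with median-ratio scaling (adjusted p = 0.0838 and 0.122).

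Genes that fell lay next to each other on the chromosome more often than random draws of tested genes, a pattern noticed in the list of genes before it was counted. Among 184 genes that fell there were 12 neighbouring pairs, against a mean of 3.18 and an upper limit of 7 for the central 95% of 10000 draws (one-sided permutation p = 0.0001, the smallest these draws can give). After removal of overlapping genes, whose reads cannot be told apart here, 10 pairs were left against a mean of 2.95 (one-sided permutation p = 0.0008). The pairs included Lrrc52 and Rxrg, 131582 bases apart on chromosome 1, Fgf3 and Fgf15, 53184 apart on chromosome 7, Lztfl1 and Ccr9, 49654 apart on chromosome 9, and Nipal1 and Txk, 24900 apart on chromosome 5. Neighbours were counted among tested genes only, so genes below the filter may lie between them. The widest pair, Dkk3 and Arntl, was 1048408 bases apart and the closest without overlap, Socs1 and Tnp2, 2399. Members of 1 family side by side, such as Fgf3 and Fgf15, were counted too. Shared regulation of neighbouring genes is a hypothesis that may account for this, and clustering of genes of like cell type in the genome was not tested against it.

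DNA carried along with the knockout allele was tested as a source of differences near Tox. Within 10 Mb of Tox, 0 of 37 tested genes passed the threshold, against 0.706 expected. A count as low has a chance of 0.49 with no such effect, so the bound set beforehand, a count at or below the expected number, was too weak to exclude it. The median log2 fold change of these 37 genes was -0.545, close to that of all tested genes (-0.518), which argues against a shift of the region as a whole. The fixed list of 16 genes around Tox ranked higher than other genes in camera under 12 of 24 settings. It did not with an estimated correlation (camera adjusted p = 0.598). An effect of carried DNA on single genes stays open.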
